A study of Homo sapiens with 20 samples.

How the data were processed

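RNA of HT-29 cells, an established human colorectal cancer cell line, was measured on one-colour human Agilent arrays with probes of 60 bases. The 20 arrays fell into 5 growth conditions of 4 arrays each, as the labels give them: tissue culture plastic, Matrigel (a basement membrane extract of mouse tumour), liver biomatrix and lung biomatrix (the matrix left after rat organs are stripped of their cells), and in vivo liver metastases, which grew in nude mice after injection of the cells into the spleen. The scanner files hold the Cy3 signal of each spot as an intensity, per the file headers, with background subtraction and detrending but no scaling between arrays. Agilent Feature Extraction made them, version 10.7 in the submitters' processing notes and 10.7.3.1 per the file headers, with grid coordinates of build hg19. The authors also deposited a table of log2 values of the same arrays. Set against the scanner signals, these deposited values were log2 signals less the 75th percentile of each array, centred on the median of each probe, with correlations of 0.9987 to 0.9998 per array. The fit below started from the scanner signals, and the deposited log2 values served as an alternative.

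The 58717 spots that were not controls stood for 42405 probes. Spots marked as non-uniform or as population outliers were left out, replicate spots of a probe were averaged, and each log2 signal was taken less the 75th percentile of its array. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 32275 probes. After probes with no gene name and 68 probes with too many marked spots were left out, 30924 probes entered. The probe with the highest mean stood for each gene, which gave 25322 genes tested, 16314 of them with a current symbol. Symbols were brought up to date with a table of RefSeq names on GRCh38.p14, used for names only, and coordinates are those of the probes in the files (hg19). Between 61.1% and 75.2% of probes were well above background per array, the 75th percentile of the signal lay between 1445 and 5945, between 331 and 747 spots per array were marked, and 0 spots were saturated. The 4 arrays per group limit the precision.

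One limma 3.58.1 fit (R 4.3.3, data.table version 1.17.8) with 5 group means over all 20 arrays gave the 10 pairwise comparisons, with 15 residual degrees of freedom and a prior of 2.66. The p-values were adjusted by Benjamini-Hochberg over the 25322 genes of each comparison. A gene was called when its adjusted p was under 0.05 and its log2 difference at least 1 in size. Differences are given on the log2 scale with limma's moderated standard error. Where no array of 1 of the groups was well above background, a fold is given as at least the ratio to the mean, over its arrays, of the higher of the probe's own signal and the lowest signal called well above background on that array. On simulated data with 100 genes changed by 1.5 and 100 by 3 on the log2 scale, the fit called 77% and 97% of them, and 5 of the unchanged genes.

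For each of 6 main comparisons, the named genes were the 8 largest rises and 8 largest falls among called genes with a symbol whose 2 groups of arrays did not overlap and whose probe was well above background on at least 3 of 4 arrays of at least 1 group. For each of 4 secondary comparisons they were the 3 largest of each. To these were added up to 3 called members with the largest change of each gene list that passed its test, and the 2 members with the largest change of any other list described. The comparisons, tests, alternatives, this rule and the 37 gene lists were chosen before the data were examined, except where the text says otherwise. The lists covered mitosis, DNA replication, hypoxia response, glycolysis, oxidative phosphorylation, cholesterol synthesis, fatty acid oxidation and ketogenesis, colonocyte differentiation, goblet and secretory cells, intestinal stem cells and WNT targets, epithelial junctions, mesenchymal transition, integrins and matrix receptors, laminins and basement membrane, matrix proteases and inhibitors, interferon response, antigen presentation, NF-kB and chemokines, immediate early and AP-1 genes, and targets of MAPK feedback, TGF-beta, YAP and p53. They also covered the unfolded protein response, the amino acid response (ATF4), heat shock, NRF2 targets, drug metabolism and transport, metallothioneins and zinc, tumour antigens and prognosis genes of colon cancer, markers of hepatocytes, fibroblasts and stellate cells, endothelium, leukocytes, erythroid cells and lung epithelium, and housekeeping genes. Lists were tested with camera (preset correlation 0.01), adjusted over the 37 lists of a comparison, and again with the correlation estimated from the data and with fry. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

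The distance of each culture to the in vivo metastases was the mean over genes of the squared difference of group means, less the sampling variance of both means. The difference between 2 cultures in this distance was tested by an exact two-sided permutation test over the 70 assignments of their 8 arrays, adjusted over 6 pairs, on genes with a value on all arrays. Genes called the same way in 2 comparisons against plastic were set beside the overlap of independent lists and beside fits with the plastic arrays split 2 and 2. They were also set beside simulated unchanged groups that shared one simulated plastic group. The labels do not say that arrays of equal number were handled together. Over 40 pairs of arrays of equal number, the median correlation of their deviations from the group means was 0.008 (from -0.129 to 0.275). Arrays were therefore not paired, and a fit with the replicate number as a block was an alternative.

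The other alternatives were normexp background correction (offset 50), quantile normalization, both together, scaling to the median of each array, no filter on dim probes, only probes well above background on all 20 arrays, the mean of all probes of a gene, fits of only the 2 groups compared, limma with trend and robust moderation, array weights, the slide as a block, limma's treat, other measures of distance, and leaving out each array in turn. Chosen after seeing the data were fits without probes that carry a run of 7 or more bases of alternating G and A, and fits without Matrigel arrays 2, 3 and 4 and plastic array 4. Transcripts that mark the sex of a sample were left out of the tests and are not reported here. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.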

Results

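The series profiled HT-29 cells with 4 arrays each on plastic, Matrigel, liver biomatrix and lung biomatrix and in liver metastases in nude mice, 20 arrays in all. Signals are log2 values less the 75th percentile of their array. Across genes well above background on all 20 arrays, each array correlated with its group at a mean of 0.975 or higher and with any array of another group at 0.968 or lower, where genes are not independent replicates. The first 3 principal components carried 32.9%, 23.7% and 16.1% of the variance. Liver and lung biomatrix shared slide 1, the in vivo metastases were alone on slide 2, and Matrigel and plastic shared slide 3. Only liver against lung biomatrix and Matrigel against plastic thus lie within a slide. There lung biomatrix and Matrigel filled row 1 and liver biomatrix and plastic row 2. Row cannot be told apart from group there, nor slide from group in the other comparisons. The fit's p-values and ± values pool the spread between arrays over all 5 groups, not only the 2 compared. For SLC14A1 at ± 1.39 the standard deviations were 0.15 on lung biomatrix and 0.11 on plastic. For HSPA6 at ± 0.89 they were 0.82 on Matrigel and 2.68 on plastic.

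Some features of the arrays bear on genes named below. On Matrigel arrays 2, 3 and 4, between 11 and 15 of 27 hepatocyte markers lay 2 or more log2 units above the highest of plastic arrays 1 to 3, against 1 of 27 on Matrigel array 1 and on plastic array 4. Among genes whose probe carries a run of 10 or more bases of alternating G and A (33 genes), the median log2 signal was 4.69 on Matrigel, 2.84 on plastic, 1.96 on liver biomatrix, 1.47 in vivo and -2.49 on lung biomatrix. The metastases grew in mouse tissue, and against plastic 10 of 18 fibroblast and stellate markers rose in them (adjusted p = 0.00352 with an estimated correlation). The median log2 difference of all 25322 genes lay between -0.20 and 0.11 across the 10 comparisons. It lay at -0.46 to 0.26 with arrays scaled to their median, -0.12 to 0.04 with quantile normalization and -0.59 to 0.31 with normexp background correction. The mean change of every list called below kept its sign under these scalings.

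**Figure D1:**
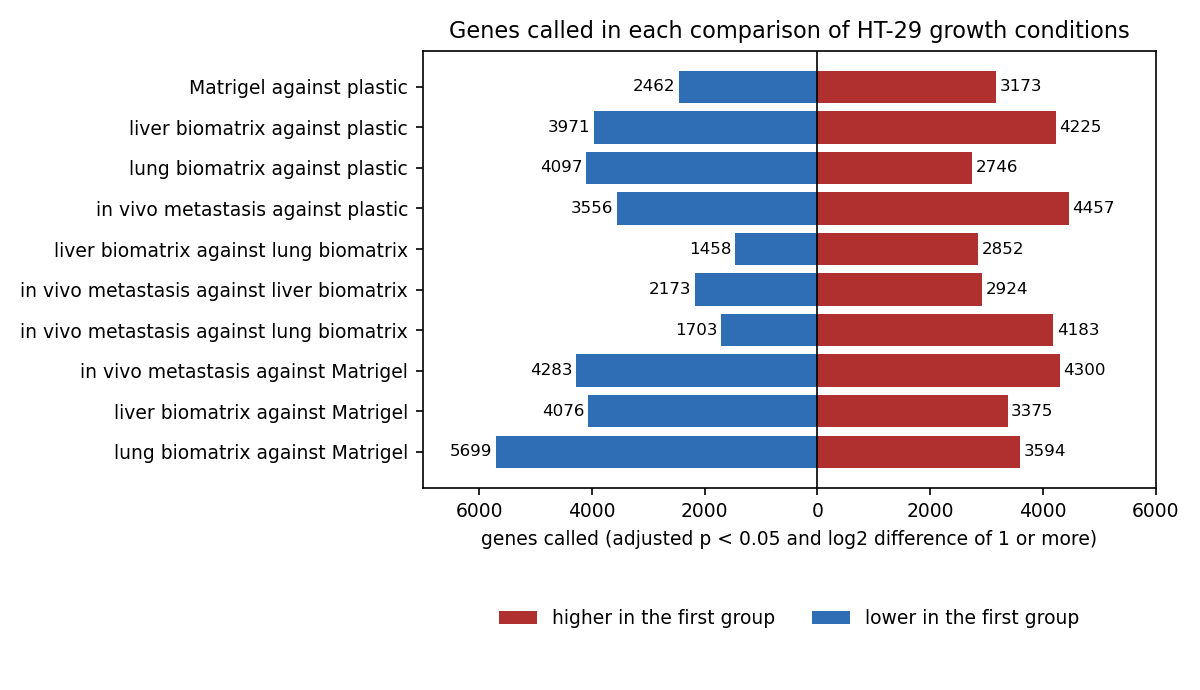
Genes called higher and lower in each of the 10 comparisons (bars, number of genes of 25322 tested, 4 arrays per group). The counts lie between 4310 for liver against lung biomatrix and 9293 for lung biomatrix against Matrigel.

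Matrigel against plastic asked how HT-29 cells on a basement membrane gel differ from the same cells on plastic. All 25 hypoxia genes and 22 of 27 NF-kB targets and chemokines (1 lower) were called higher on Matrigel, and 8 of 12 genes of metallothioneins and zinc lower (n = 4 arrays per group). With an estimated correlation these list calls were lost (adjusted p = 0.078, 0.0576 and 0.0576). The heat-inducible chaperone HSPA6 rose by 6.33 ± 0.89 on the log2 scale, an 80.6-fold change, with its other probes at 0.32 and 4.95. ANGPTL4, an inhibitor of lipoprotein lipase (chromosome 19, probe at 8439197 to 8439256), rose by 6.25 ± 0.65. Rises of similar size were found for the ubiquitin-like modifier UBD (6.12 ± 0.92), the matrix protein SPON1 (5.95 ± 0.82), the acute-phase protein SAA2 (6.01 ± 0.80, at least 55.6-fold), the basement membrane protein NID1 (5.82 ± 0.82, at least 52.3-fold), the heparan sulfate sulfotransferase HS6ST2 (at least 56.4-fold, other probe 1.14) and the fatty acid elongase ELOVL5 (at least 49.2-fold). The difference of UBD, HS6ST2 and ELOVL5 was 2.60, 1.74 and 0.43, with no call, when Matrigel arrays 2, 3 and 4 and plastic array 4 were left out, and that of SPON1 and NID1 was 2.58 and 3.72, still called. The largest falls were those of the cytokine IL33 (-6.33 ± 0.71), the neuroendocrine transcription factor INSM1 (-6.31 ± 0.43, at least 56.8-fold), LRRC74B (listed as LOC400891, -6.26 ± 0.54, at least 57.8-fold), the pore-forming claudin CLDN2 (-5.43 ± 0.55), the cation channel PKD2L1 (-5.20 ± 0.48, other probe -1.79), the transcription factor NEUROD2 (-5.20 ± 0.49), the phospholipase PLCB2 (-4.98 ± 0.31) and LRRIQ1 (-4.92 ± 0.34, at least 24.6-fold, other probe -4.38). The 2 groups of arrays did not overlap for 48.6% of all genes, where chance gives 2.86%. In all, 5635 of 25322 genes were called, 3173 higher and 2462 lower, and 12131 had an adjusted p under 0.05 alone. The share of called genes that were higher was 56.3%, and 63.1% with normexp. It was 47.1% with quantile normalization, 47.9% with arrays scaled to their median and 49.6% with normexp and quantile normalization.

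All 25 measured hypoxia genes rose, also when adjusted over the list alone, with a median of 3.14 (adjusted p = 2.52e-15, and adjusted p = 0.078 with an estimated correlation). They included ANGPTL4, the glucose transporter SLC2A3 (6.24 ± 1.31) and STC2 (5.62), but without Matrigel arrays 2, 3 and 4 and plastic array 4 the last pair differed by 0.45 and 0.47 and were not called. The list mean was 2.69 on Matrigel array 1, between 4.00 and 4.08 on the other Matrigel arrays and between 0.13 and 0.85 on plastic. Of 16 glycolysis genes 10 rose, and adjusted over the list alone also 10, among them ENO2 (3.93 ± 0.24), ALDOC (2.86 ± 0.17) and ALDOA (2.45 ± 0.17), with adjusted p = 5.89e-07, and adjusted p = 0.0631 with an estimated correlation. Of 27 NF-kB targets and chemokines 22 rose and 1 fell, and adjusted over the list alone the same numbers, with CCL20 at 4.90 ± 0.41, CXCL8 at 4.69 ± 0.42 and CXCL1 at 4.44 ± 0.38 (adjusted p = 1.63e-09, and adjusted p = 0.0576 with an estimated correlation). Of 21 immediate early and AP-1 genes 15 rose and 1 fell (adjusted over the list alone 15 and 1), including ATF3, NR4A1 and FOSL1 (3.51, 3.31 and 3.11), with adjusted p = 3.34e-07, and adjusted p = 0.0631 with an estimated correlation. Of 20 genes of the unfolded protein response 14 rose (adjusted over the list alone 14). Among them were the chaperone helpers DNAJC3 (3.35 ± 0.23) and DNAJB9 (3.02 ± 0.25), and the list had adjusted p = 7.54e-10, and adjusted p = 0.102 with an estimated correlation. Of 25 genes of the amino acid response 15 rose (adjusted over the list alone 15). Among them were CHAC1 (4.28 ± 0.27) and DDIT3 (4.17 ± 0.27), and the list had adjusted p = 2.06e-09, and adjusted p = 0.0576 with an estimated correlation.

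Of 12 genes of metallothioneins and zinc 8 fell (adjusted over the list alone 8), led by MT1G (-2.74 ± 0.50), MT1E (-2.42 ± 0.14) and MT1M (-2.29 ± 0.17), with adjusted p = 5.89e-07, and adjusted p = 0.0576 with an estimated correlation. Of 25 DNA replication genes 12 fell and 1 rose (adjusted over the list alone 12 and 1), with MCM6 at -1.46 and MCM5 at -1.40 (adjusted p = 2.56e-07, and adjusted p = 0.249 with an estimated correlation). Of 20 intestinal stem cell genes and WNT targets 8 fell and 1 rose (adjusted over the list alone 8 and 1), with the crypt receptor EPHB3 at -2.77, ASCL2 at -2.66 and SP5 at -2.55 (adjusted p = 0.000939, and adjusted p = 0.191 with an estimated correlation). Of 20 antigen presentation genes 9 rose (adjusted over the list alone 9). Among them were HLA-C (2.21), PSMB9 (2.14) and TAP1 (1.96), and the list had adjusted p = 0.000186, and adjusted p = 0.119 with an estimated correlation. Of 22 matrix proteases and inhibitors 10 rose and 1 fell (adjusted over the list alone 11 and 1). Among them were the collagenase MMP1 (4.22 ± 0.45) and the urokinase receptor PLAUR (2.94 ± 0.17), and the list had adjusted p = 0.000463, and adjusted p = 0.0576 with an estimated correlation. The protease inhibitor TIMP3, of the same list, rose by 4.01 ± 1.04, but stood at -0.96 without Matrigel arrays 2, 3 and 4 and plastic array 4. Of 27 hepatocyte markers 15 rose, and adjusted over the list alone 16, with ALB at 7.68, APOA2 at 5.93 ± 1.51 and FGG at 5.29 ± 1.03 (at least 39-fold), with adjusted p = 0.000535, and adjusted p = 0.286 with an estimated correlation. The mean of this list was 0.34 above plastic and not called (adjusted p = 0.505) without Matrigel arrays 2, 3 and 4 and plastic array 4, where ALB stood at 1.20, still called, APOA2 at -0.03 and FGG at 1.18.

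Of 27 colonocyte differentiation genes 12 rose and 1 fell, among them the carcinoembryonic antigen CEACAM5 (3.63 ± 0.38), APOA4 (5.21 ± 1.15) and the chloride exchanger SLC26A3 (3.81 ± 0.93, at least 14.1-fold). Without Matrigel arrays 2, 3 and 4 and plastic array 4, APOA4 stood at 0.23 and SLC26A3 at -0.15. Of 24 epithelial junction genes 6 rose and 2 fell, among them CDH17 (3.66) and OCLN (2.08) with rises and CLDN2 with a fall. Of 20 laminins and basement membrane genes 8 rose and 1 fell, among them NID1, LAMA1 (at least 18.2-fold) and, as the fall, COL4A4 (at least 12.3-fold). Adjusted p was 0.00304, 0.0024 and 0.00709 for these 3 lists, and adjusted p = 0.286, 0.249 and 0.0942 with an estimated correlation. Adjusted over the list alone the counts were the same. Without Matrigel arrays 2, 3 and 4 and plastic array 4 the means of the colonocyte and junction lists went from 1.26 to 0.69 and from 0.47 to 0.25, and both lost their call (adjusted p = 0.148 and 0.0756). Some members also rose among TGF-beta targets (5 of 16, with BHLHE40 at 3.32 and IL11 at 2.61), MAPK feedback targets (8 up, 1 down of 19, DUSP5 at 3.79), heat shock genes (5 up, 1 down of 20, CRYAB at 3.49) and NRF2 targets (8 up, 1 down of 22, GSR at 2.07 and ABCC2 at 4.03). Their adjusted p was 0.00508, 0.00706, 0.011 and 0.00145, and adjusted p = 0.249, 0.207, 0.387 and 0.0576 with an estimated correlation. The interferon response (9 up, 1 down of 28), YAP targets (8 up, 2 down of 19), fatty acid oxidation and ketogenesis (3 up, 5 down of 19) and mitosis (1 down of 22) passed narrowly, with adjusted p of 0.0485, 0.0487, 0.0485 and 0.0418, and adjusted p = 0.626, 0.237, 0.387 and 0.626 with an estimated correlation. Each lost its call when single arrays were left out, 12, 11, 7 and 4 arrays in turn, with adjusted p up to 0.234, 0.0569, 0.0667 and 0.0924. Without Matrigel arrays 2, 3 and 4 and plastic array 4 these 4 lists lost their call too (adjusted p = 0.886, 0.103, 0.0659 and 0.865), with means that went from 0.62 to 0.13, from 0.62 to 0.43, from -0.11 to -0.23 and from -0.29 to 0.10. There MAPK feedback targets lost their call (adjusted p = 0.0635) with a mean of 0.65 after 0.85, and ABCC2 stood at 1.55, still called. The lists with no call were oxidative phosphorylation (0 of 23 genes called), cholesterol synthesis (7 up, 3 down of 25), goblet and secretory cells (7 up, 5 down of 20), mesenchymal transition (5 up, 2 down of 14), integrins and matrix receptors (3 up, 3 down of 20), p53 targets (9 up, 2 down of 20), drug metabolism and transport (2 up, 5 down of 23) and tumour antigens and prognosis genes (6 up, 2 down of 19). The same held for markers of fibroblasts and stellate cells (5 up, 1 down of 18), endothelium (3 up, 2 down of 12), leukocytes (4 up, 2 down of 16), erythroid cells (2 up of 9) and lung epithelium (2 up, 3 down of 15), and for housekeeping genes (2 up of 16). In all 23 lists passed, 18 upward and 5 downward, and 0 passed with an estimated correlation, while fry passed 29. Without Matrigel arrays 2, 3 and 4 and plastic array 4, 3987 genes were called, 3302 of them called the same way with all arrays, where the lone Matrigel array is assumed to vary like the other groups. With the replicate number as a block 5622 genes were called.

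**Figure D2:**
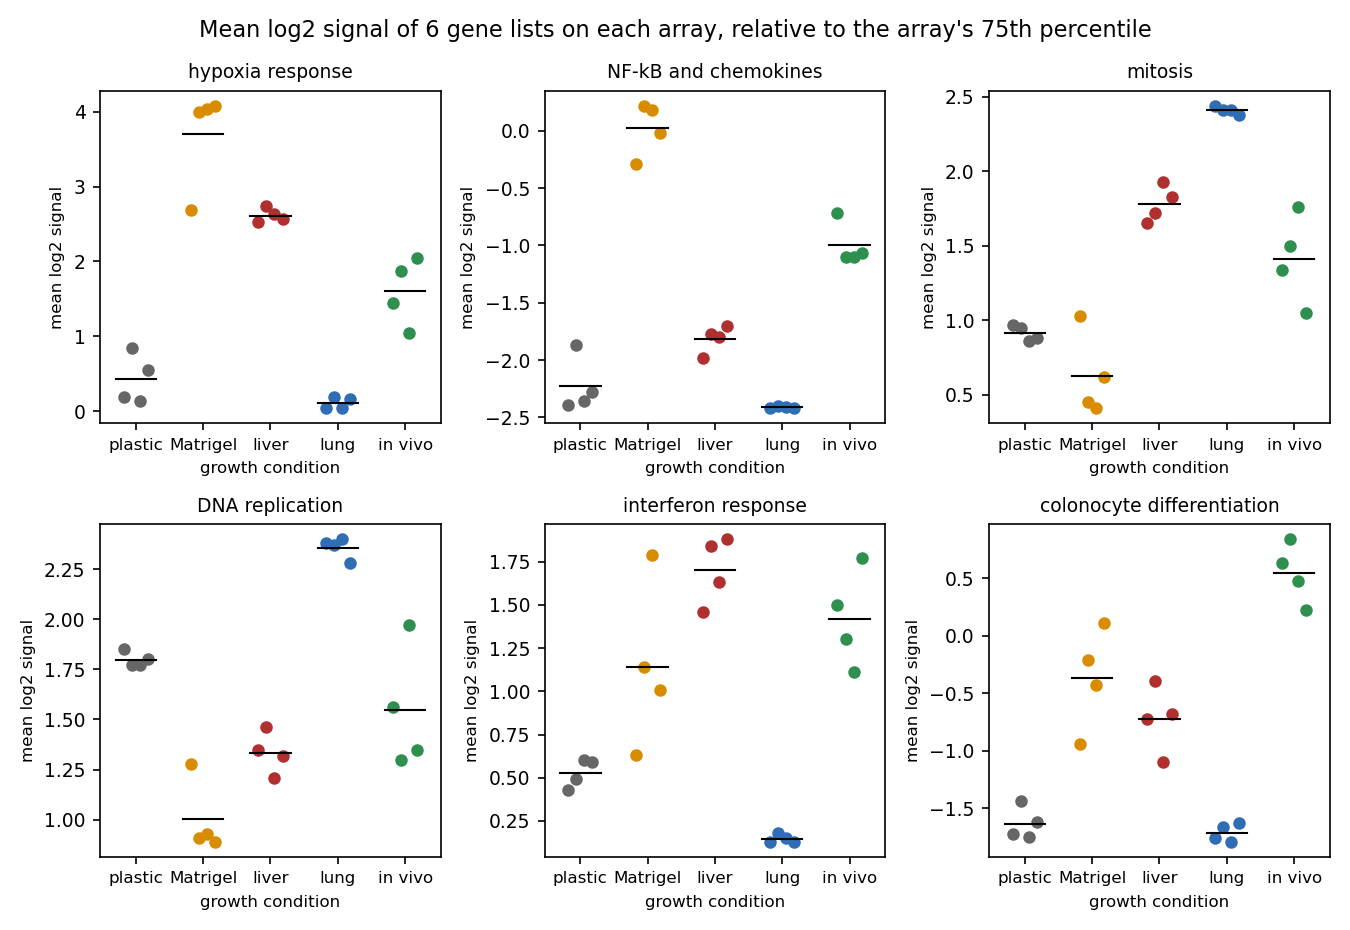
Mean log2 signal of 6 gene lists on each array, relative to the 75th percentile of the array, by growth condition (points are arrays, lines are group means, 4 arrays per group). The hypoxia list lies between 2.69 and 4.08 on Matrigel, between 0.13 and 0.85 on plastic and at 0.19 or lower on lung biomatrix.

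Liver biomatrix against plastic asked how growth on matrix of the target organ of the metastases differs from plastic. On liver biomatrix 22 of 25 hypoxia genes and 11 of 16 glycolysis genes were called higher (n = 4 arrays per group). With an estimated correlation both list calls were lost (adjusted p = 0.457 and 0.154). The crystal-forming galectin CLC rose by 8.07 ± 0.71 on the log2 scale (at least 233-fold), the claudin CLDN18 by 6.98 ± 1.21, C17orf78 by 6.95 ± 0.95 and GPR15LG (listed as C10orf99), a ligand of the receptor GPR15, by 6.32 ± 0.65. ANGPTL4 rose by 5.91 ± 0.65, a 60.3-fold change. HAPLN2 (73.4-fold), TMEM95 (5.93 ± 0.41) and LOC389834 (5.83 ± 0.39, but between -1.35 and 0.82 on its 6 other probes and 0.93 with the mean of all probes) also rose. The largest falls were those of C4orf51 (-4.69 ± 0.71, on a probe with a run of 8 bases of alternating G and A), PKD2L1 (-4.54 ± 0.48, other probe -2.41), the prohormone convertase PCSK1 (-4.43 ± 0.55, at least 21.6-fold), TSNAXIP1 (-4.28 ± 0.41, at least 19.4-fold), the kinesin KIF19 (-4.23 ± 0.41, other probe -2.78), LRRC74B (-4.21 ± 0.54), the keratin KRT17 (-4.19 ± 0.44) and PRR22 (-4.12 ± 0.36). In all, 8196 genes were called, 4225 higher and 3971 lower, and 15394 had an adjusted p under 0.05 alone.

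Of 25 hypoxia genes 22 rose (adjusted over the list alone 22), among them the vasodilator peptide ADM (4.22 ± 0.39) and ANGPTL4, with a median of 2.40 (adjusted p = 2.03e-09, and adjusted p = 0.457 with an estimated correlation). Of 16 glycolysis genes 11 rose (adjusted over the list alone 11). Among them were ENO2 (3.69 ± 0.24) and ALDOC (3.05 ± 0.17), and the list had adjusted p = 3.64e-07, and adjusted p = 0.154 with an estimated correlation. Of 28 interferon response genes 12 rose, and adjusted over the list alone 13, with the antiviral membrane protein IFITM1 at 4.37 ± 0.48, IFI44L at 3.66 ± 0.64 and IFI27 at 2.64 ± 0.19 (adjusted p = 0.000242, and adjusted p = 0.693 with an estimated correlation). Of 20 antigen presentation genes 10 rose and 2 fell (adjusted over the list alone 10 and 2). Among them were HLA-C (2.36 ± 0.14), HLA-E (2.00 ± 0.13) and HLA-B (1.92 ± 0.14, on a probe with a run of alternating G and A), and the list had adjusted p = 0.00641, and adjusted p = 0.457 with an estimated correlation. Of 22 matrix proteases and inhibitors 11 rose (adjusted over the list alone 11). Among them were urokinase PLAU (3.81 ± 0.38), cathepsin CTSB (3.07 ± 0.15) and TIMP1 (2.49 ± 0.27), and the list had adjusted p = 0.00137, and adjusted p = 0.154 with an estimated correlation. Of 20 intestinal stem cell genes and WNT targets 10 fell and 1 rose (adjusted over the list alone 10 and 1), with EPHB3 at -3.10, the cyclin CCND1 at -3.09 and SOX9 at -2.15 (adjusted p = 0.00538, and adjusted p = 0.457 with an estimated correlation). Of 22 mitosis genes 7 rose (adjusted over the list alone 7). One of them was the proliferation marker MKI67 (2.25 ± 0.22), and the list had adjusted p = 0.000242, and adjusted p = 0.693 with an estimated correlation. Of 25 DNA replication genes 6 fell (adjusted over the list alone 6). Among them were CDC6 (-1.29) and FEN1 (-2.02, on a probe with a run of alternating G and A), and the list had adjusted p = 0.0226, and adjusted p = 0.797 with an estimated correlation. Tumour antigens and prognosis genes (9 up, 1 down of 19, CEACAM5 at 4.83 and CEACAM6 at 4.30), housekeeping genes (4 up of 16, B2M at 1.64), oxidative phosphorylation (4 up, 1 down of 23, NDUFA1 at 1.59) and epithelial junctions (7 up, 1 down of 24, CDH17 at 2.98) passed with adjusted p of 0.0372, 0.0295, 0.0372 and 0.0463, and adjusted p = 0.693, 0.693, 0.797 and 0.734 with an estimated correlation. Adjusted over the list alone these 4 lists had the same counts. The antigen list lost its call without plastic array 2 (adjusted p = 0.0513), oxidative phosphorylation without plastic array 4 (adjusted p = 0.051), and without Matrigel arrays 2, 3 and 4 and plastic array 4 (mean 0.43 before and 0.37 after, adjusted p = 0.0558), and epithelial junctions without any of 5 arrays (adjusted p up to 0.0675). In all 12 lists passed, 10 upward and 2 downward, and 0 with an estimated correlation. With the replicate number as a block 8194 genes were called. Slide and group cannot be told apart here.

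Lung biomatrix against plastic posed the same question for the matrix of an organ other than the site of these metastases. The 8 largest falls were all read on probes with a repeat of G and A (n = 4 arrays per group). Of 22 mitosis genes 20 rose, and adjusted over the list alone 20, with MKI67 at 3.18 ± 0.22 and the spindle motor KIF11 at 2.05 ± 0.16 (adjusted p = 6.3e-12, and adjusted p = 0.636 with an estimated correlation). The list mean lay between 2.38 and 2.44 on the lung biomatrix arrays and between 0.86 and 0.97 on plastic. Of 25 DNA replication genes 7 rose (adjusted over the list alone 7). Among them were the licensing factor CDT1 (1.74 ± 0.15) and TYMS (1.66 ± 0.22), and the list had adjusted p = 0.000962, and adjusted p = 0.987 with an estimated correlation. Of 25 genes of the amino acid response 11 rose (adjusted over the list alone 11). Among them were CHAC1 (3.04 ± 0.27) and the serine synthesis enzymes PSAT1 (2.05 ± 0.15) and PSPH (2.03 ± 0.16), and the list had adjusted p = 5.7e-05, and adjusted p = 0.636 with an estimated correlation. Of 23 genes of oxidative phosphorylation 3 rose (adjusted over the list alone 3), NDUFB3, ATP5F1B and UQCRC2 (1.38, 1.18 and 1.14), with adjusted p = 8.94e-05, and adjusted p = 0.636 with an estimated correlation. Among 19 MAPK feedback targets 5 rose and 2 fell (adjusted over the list alone 5 and 2), the falls being CCND1 (-2.46) and EPHA4 (-2.31), with adjusted p = 0.0431, and adjusted p = 0.636 with an estimated correlation. That call was lost without plastic array 3 (adjusted p = 0.0777) and without 3 other arrays. The hypoxia list had 2 rises and 5 falls of 25 with no call, with NDRG1 at -2.43 ± 0.33.

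Among single genes, TMEM95 (6.01 ± 0.41), the potassium channel partner KCNIP4 (63.9-fold), HAPLN2 (5.63 ± 0.32), the histone genes H3C15 (listed as HIST2H3A, 5.91 ± 0.63) and H2BC7 (listed as HIST1H2BF, 5.74 ± 0.46), AMOTL1 (5.57 ± 0.68), the collagen gene COL11A2 (5.52 ± 0.41) and the urea transporter SLC14A1 (5.32 ± 1.39) rose most on lung biomatrix. The other probes of COL11A2 gave -0.53 and -0.33, while those of SLC14A1 gave 4.90 and 5.62. The 8 largest falls were those of RNF150 (-7.71 ± 0.78, at least 209-fold), KRT79 (-7.06 ± 0.70), ZNF840P (-6.64 ± 0.72), ACKR5 (listed as GPR182, -6.56 ± 0.69), HMBOX1 (-6.46 ± 0.58), GPR179 (-6.41 ± 0.60), BICC1 (-6.39 ± 0.79) and MAGEB6 (-6.08 ± 0.74, at least 67.2-fold). Their probes carry runs of 8 to 12 bases of alternating G and A, and the 3 other probes of HMBOX1 gave between -0.59 and 0.30. In all, 6843 genes were called, 2746 higher and 4097 lower, and 14278 had an adjusted p under 0.05 alone. Without the probes with such runs 6678 were called. The share of called genes that were higher was 40.1%, but 66.1% with arrays scaled to their median, 50.2% with quantile normalization and 50.4% with normexp and quantile normalization. In all 5 lists passed, all upward, and 0 with an estimated correlation, while 6840 genes were called with the replicate number as a block.

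In vivo metastasis against plastic asked how the cells differ between the tumour in the animal and the dish. In the metastases 10 of 18 fibroblast and stellate markers and 16 of 27 colonocyte genes were called higher, with 1 colonocyte gene lower (n = 4 arrays per group). With an estimated correlation the former list call held (adjusted p = 0.00352) and the latter was lost (adjusted p = 0.236). Decorin (DCN, chromosome 12, probe at 91539834 to 91539893) rose by 11.76 ± 0.31 on the log2 scale (other probe 5.94), COL1A2 by 11.39 ± 0.28 (at least 2300-fold) and COL1A1 by 10.76 ± 0.27, all genes of connective tissue. The haptoglobin relative HPR (10.47 ± 0.58), BTNL3 (at least 938-fold), THY1 (at least 837-fold) and the adhesion molecule NCAM1 (at least 774-fold) followed. The largest falls were those of CLEC3A (-7.44 ± 0.69, at least 143-fold), the bile acid-induced hormone FGF19 (-5.99 ± 0.41), PKD2L1 (-5.51 ± 0.48, other probe -2.40), LDLRAD2 (-4.88 ± 0.28, at least 24.3-fold), the cyclooxygenase PTGS1 (-4.81 ± 0.38, other probe -3.20), C4orf51 (-4.60 ± 0.71, on a probe with a run of 8 bases of alternating G and A), SLC60A1-AS1 (listed as LOC284578, -4.52 ± 0.53, at least 23-fold) and the endotoxin receptor TLR4 (-4.50 ± 0.40, other probe -2.85). In all, 8013 genes were called, 4457 higher and 3556 lower, and 15321 had an adjusted p under 0.05 alone.

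Of 18 fibroblast and stellate markers 10 rose, and adjusted over the list alone 10, with adjusted p = 1.09e-05, and this call held with an estimated correlation (adjusted p = 0.00352). Of 16 leukocyte markers 10 rose and 1 fell (adjusted over the list alone 10 and 1). Among them were the complement gene C1QB (8.08 ± 0.38, at least 264-fold) and, as the fall, CD14 (-2.14 ± 0.16), and the list had adjusted p = 0.0135, and adjusted p = 0.304 with an estimated correlation. Of 14 mesenchymal transition genes 9 rose and 1 fell (adjusted over the list alone 9 and 1). Among them were CDH11 (7.89 ± 0.51, at least 194-fold), CDH2 (6.12 ± 0.28) and VIM (5.60 ± 0.24), genes that fibroblasts also express, and the list had adjusted p = 0.00194, and adjusted p = 0.12 with an estimated correlation. Of 20 laminins and basement membrane genes 7 rose and 1 fell (adjusted over the list alone 7 and 1), with NID1 at 9.27 ± 0.82 (at least 573-fold) and LAMA1 at 6.60 ± 0.61 (at least 86.7-fold), with adjusted p = 0.0233, and adjusted p = 0.236 with an estimated correlation. The haemoglobin gene HBA2 stood at 8.13 ± 0.51, in an erythroid list with 3 rises of 9 and no call, and the haem carrier HPX at 7.71 ± 0.67, in a hepatocyte list with 10 rises of 27 and no call. The endothelial list had 3 rises and 2 falls of 12 with no call, and the receptor TIE1 stood at 7.26 ± 0.29 (at least 123-fold). Of 27 colonocyte differentiation genes 16 rose and 1 fell (adjusted over the list alone 16 and 1), among them the aminopeptidase ANPEP (8.74 ± 0.44), APOA4 (6.22 ± 1.15) and CEACAM5 (5.98 ± 0.38), with adjusted p = 3.48e-05, and adjusted p = 0.236 with an estimated correlation. Of 20 antigen presentation genes 12 rose and 1 fell (adjusted over the list alone 12 and 1), with HLA-DPB1 at 4.96 ± 0.50 and PSMB9 at 2.68 ± 0.25 (adjusted p = 0.000184, and adjusted p = 0.236 with an estimated correlation).

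Of 25 hypoxia genes 15 rose and 1 fell in vivo (adjusted over the list alone 15 and 1), with ANGPTL4 at 3.14 ± 0.65, VEGFA at 2.74 ± 0.38 and ADM at 2.16 ± 0.39 (adjusted p = 0.000186, and adjusted p = 0.47 with an estimated correlation). Of 27 NF-kB targets and chemokines 15 rose and 3 fell (adjusted over the list alone 15 and 3). Among them were IL32 (4.59 ± 0.34) and CXCL8 (3.57 ± 0.42), and the list had adjusted p = 0.00194, and adjusted p = 0.304 with an estimated correlation. Of 22 matrix proteases and inhibitors 10 rose (adjusted over the list alone 10). Among them were PLAU (3.36) and MMP1 (3.07), and the list had adjusted p = 0.00341, and adjusted p = 0.12 with an estimated correlation. Of 19 tumour antigens and prognosis genes 9 rose and 1 fell, and adjusted over the list alone 10 and 1. Among them were CEACAM6 (4.68) and the mucin MUC13 (3.61), and the list had adjusted p = 0.00132, and adjusted p = 0.304 with an estimated correlation. Of 24 epithelial junction genes 7 rose (adjusted over the list alone 7). Among them were CDH17 (5.04 ± 0.42) and the desmosomal cadherin DSC2 (3.57 ± 0.24), and the list had adjusted p = 0.00214, and adjusted p = 0.359 with an estimated correlation. Glycolysis (6 up of 16, ENO2 at 1.76), the interferon response (12 up of 28, IFITM1 at 5.02), mitosis (3 up of 22, MKI67 at 3.15) and intestinal stem cells and WNT targets (2 up, 8 down of 20, OLFM4 at 5.09 and EPHB3 at -2.72) also passed, with the same counts adjusted over the list alone. Their adjusted p was 0.00911, 0.0165, 0.0403 and 0.0277, and adjusted p = 0.411, 0.769, 0.793 and 0.47 with an estimated correlation. The interferon call was lost without in vivo array 4 (adjusted p = 0.0509), and the mitosis call without in vivo array 3 (adjusted p = 0.129), in vivo array 2 (0.0648) or plastic array 3 (0.0591). In all 15 lists passed, 14 upward and 1 downward. The share of called genes that were higher was 55.6%, but 39.7% with arrays scaled to their median, and 8014 genes were called with the replicate number as a block.

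**Figure D3:**
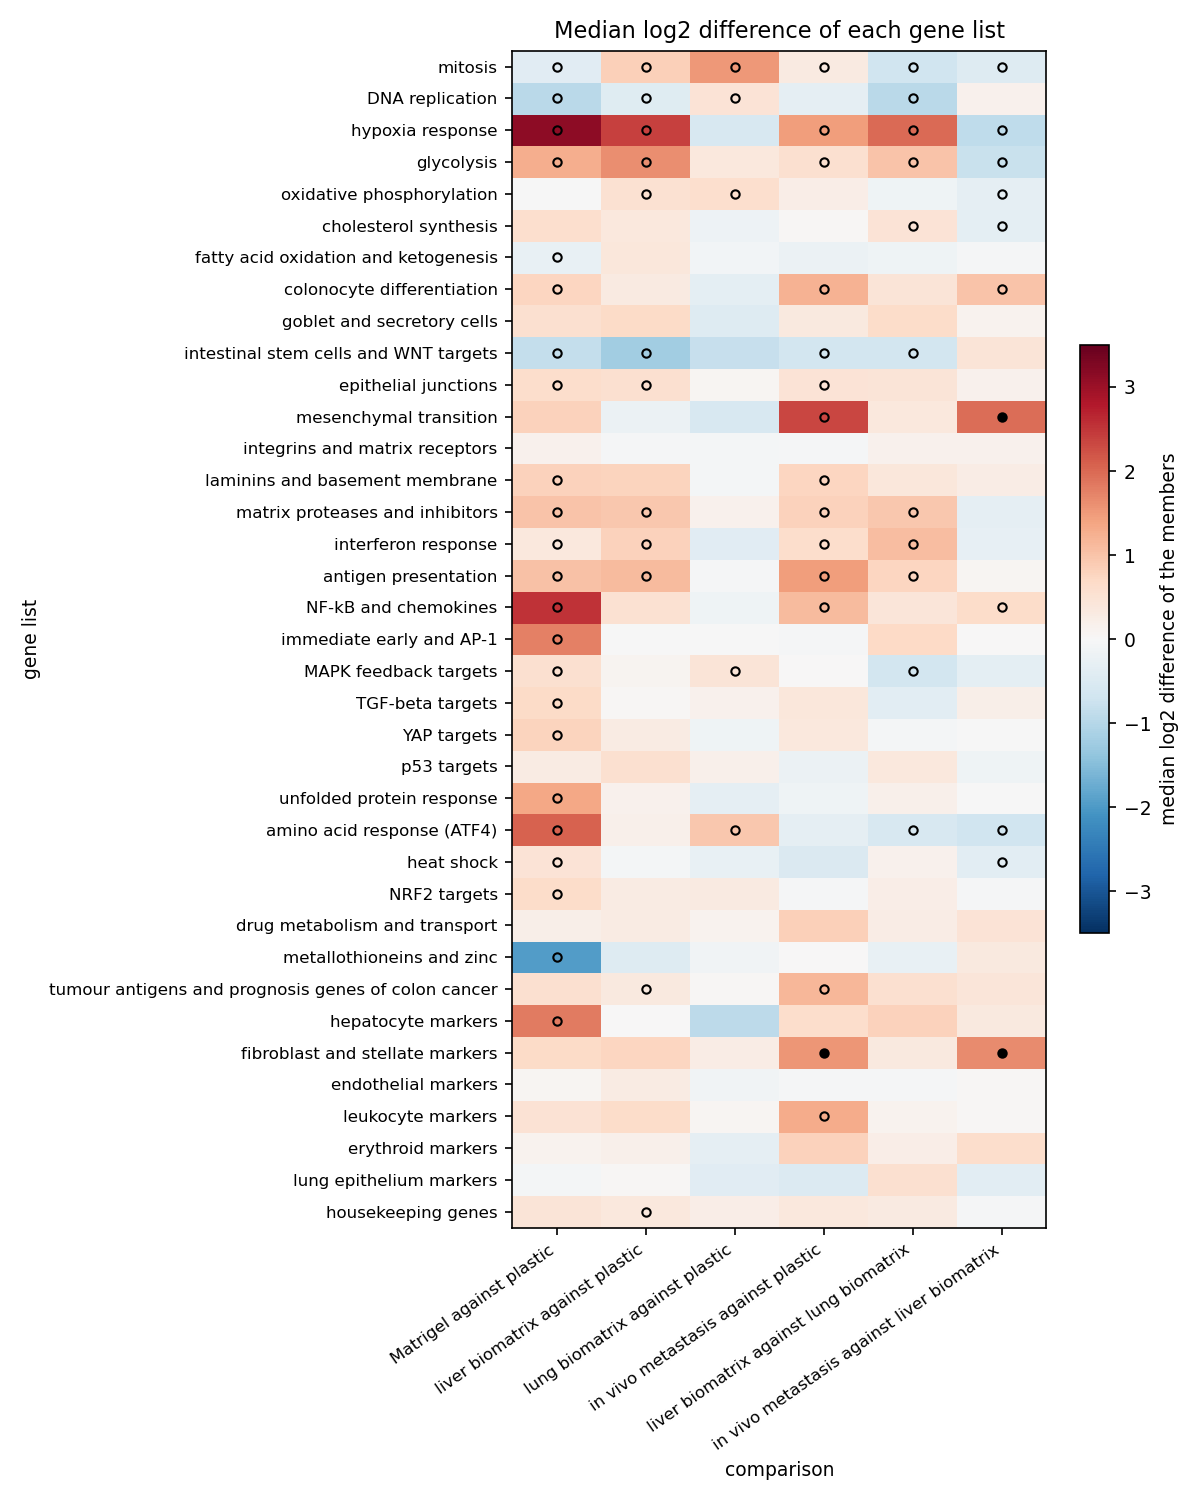
Median log2 difference of the members of each of 37 gene lists (vertical axis) in the 6 main comparisons (horizontal axis, colour scale in log2 units, 4 arrays per group). Circles mark lists that passed with the preset correlation, and filled circles those that also passed with an estimated one, which were the fibroblast markers in both in vivo comparisons and mesenchymal transition against liver biomatrix. The hypoxia list has medians of 3.14 on Matrigel and 2.40 on liver biomatrix against plastic.

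Liver biomatrix against lung biomatrix compared the matrices of 2 organs on one slide. Of 25 hypoxia genes 22 were called higher on liver biomatrix, and of 25 DNA replication genes 12 were called lower (n = 4 arrays per group). With an estimated correlation both list calls were lost (adjusted p = 0.252 and 0.293). C17orf78 was higher by 7.78 ± 0.95 on the log2 scale, ANGPTL4 by 7.48 ± 0.65 (178-fold), CLC by 6.65 ± 0.71, the bile acid transporter subunit SLC51A (listed as OSTalpha) by 6.62 ± 0.50, COXFA4L2 (listed as NDUFA4L2) by 6.61 ± 0.41, the secretoglobin SCGB2A1 by 6.48 ± 0.50, CEACAM5 by 6.16 ± 0.38 and CFAP96 (listed as C4orf47) by 6.08 ± 0.37. Lower by the most were PPP2R2C (-4.68 ± 0.45, at least 25.6-fold), the inflammasome sensor NLRP3 (-4.65 ± 0.31, other probe -3.52), the alcohol dehydrogenases ADH1A (-4.31 ± 0.41) and ADH1C (-4.17 ± 0.44), the retinol dehydrogenase RDH12 (-3.95 ± 0.25), UTS2B (listed as UTS2D, -3.90 ± 0.38), RTP3 (-3.78 ± 0.49) and the phosphatase PTPRO (-3.71 ± 0.37). In all, 4310 genes were called, 2852 higher and 1458 lower, and 10644 had an adjusted p under 0.05 alone.

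Of 25 hypoxia genes 22 were higher on liver biomatrix (adjusted over the list alone 22), with NDRG1 and ADM both at 4.83, and a median of 1.99 (adjusted p = 3e-14, and adjusted p = 0.252 with an estimated correlation). Of 16 glycolysis genes 8 were higher (adjusted over the list alone 8). Among them were ENO2 (4.25) and ALDOC (3.83), and the list had adjusted p = 3.54e-06, and adjusted p = 0.252 with an estimated correlation. Of 28 interferon response genes 15 were higher (adjusted over the list alone 15). Among them were IFITM1 (4.39), IFI44L (4.36) and IFI6 (3.87), and the list had adjusted p = 1.87e-09, and adjusted p = 0.357 with an estimated correlation. Of 22 matrix proteases and inhibitors 10 were higher (adjusted over the list alone 10). Among them were PLAU (3.23) and the collagenase MMP13 (at least 7.13-fold), and the list had adjusted p = 0.000263, and adjusted p = 0.0925 with an estimated correlation. Of 20 antigen presentation genes 7 were higher, and adjusted over the list alone 8. One of them was PSMB9 (2.36), and the list had adjusted p = 0.000371, and adjusted p = 0.293 with an estimated correlation. Of 25 DNA replication genes 12 were lower (adjusted over the list alone 12), with MCM5 at -1.70 and E2F1 at -1.56 (adjusted p = 5.53e-13, and adjusted p = 0.293 with an estimated correlation). Of 22 mitosis genes 2 were lower (adjusted over the list alone 2), PLK1 (-1.57) and AURKB (-1.19, but -0.99 and not called without liver biomatrix array 4), with a median of -0.71 over the list (adjusted p = 7.56e-06, and adjusted p = 0.541 with an estimated correlation). Of 25 genes of the amino acid response 11 were lower and 4 higher (adjusted over the list alone 11 and 4), among them the amino acid transporter SLC7A5 (-2.48) and PCK2 (-2.57), with adjusted p = 0.000514, and adjusted p = 0.357 with an estimated correlation. MAPK feedback targets (4 lower, 1 higher of 19, DUSP5 at 2.81), intestinal stem cells and WNT targets (5 lower, 1 higher of 20, SMOC2 at 2.64 and SP5 at -1.60) and cholesterol synthesis (6 higher of 25, MSMO1 at 2.96) passed with adjusted p of 0.0214, 0.0291 and 0.0259, and adjusted p = 0.357, 0.549 and 0.627 with an estimated correlation. Adjusted over the list alone these 3 had the same counts, and the cholesterol call was lost without liver biomatrix array 1 (adjusted p = 0.0638). In all 11 lists passed, 6 upward and 5 downward, and 0 with an estimated correlation. The share of called genes that were higher on liver biomatrix was 66.2%, but 42.4% with arrays scaled to their median, 53.2% with quantile normalization and 77.5% with limma's treat. With the replicate number as a block 4303 genes were called. With the slide as a block 4315 were called, but that fit holds the same 5 group means, so its count could hardly differ and does not test slides.

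In vivo metastasis against liver biomatrix compared tumours in the liver with cells on the matrix of that organ. Of 18 fibroblast and stellate markers 9 were called higher in vivo and 1 lower, and of 14 mesenchymal transition genes 8 higher and 1 lower (n = 4 arrays per group). Both list calls held with an estimated correlation (adjusted p = 0.0108 and 0.035). The largest rises were those of DCN (11.50 ± 0.31, other probe 5.68), COL1A2 (at least 2360-fold), the connective tissue gene AEBP1 (at least 852-fold), NCAM1 (at least 801-fold), HPR (9.47 ± 0.58), THY1 (9.20 ± 0.50) and the complement inhibitor CFI (at least 414-fold). CLEC3A fell by 10.11 on the log2 scale (at least 914-fold). Other falls were those of the zinc finger genes ZNF793 (at least 84.5-fold), ZNF569 (at least 80.4-fold) and ZNF260 (at least 66-fold, with the other probe at -3.04), the succinate receptor SUCNR1 (-6.51 ± 0.71), CLC (-6.19 ± 0.71), the growth factor IGF2 (-5.82 ± 0.61, with the other probe at -4.58) and the mucin MUC21 (at least 39.7-fold). In all, 5097 genes were called, 2924 higher and 2173 lower, and 12284 had an adjusted p under 0.05 alone.

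Of 18 fibroblast and stellate markers 9 rose and 1 fell (adjusted over the list alone 9 and 1), with adjusted p = 6.11e-05, and adjusted p = 0.0108 with an estimated correlation, so this call held. Of 14 mesenchymal transition genes 8 rose and 1 fell (adjusted over the list alone 8 and 1). Among them were CDH11 (at least 198-fold), ZEB2 (at least 167-fold) and CDH2 (6.74 ± 0.28), and the list had adjusted p = 9.96e-05, and adjusted p = 0.035 with an estimated correlation, so this call held too. On probes well above background on all 20 arrays both calls were lost, with means of 1.60 after 3.39 for the fibroblast list (adjusted p = 0.184) and 1.40 after 2.82 for the mesenchymal list (adjusted p = 0.0922). In the same samples the haemoglobin gene HBA2 stood at 7.93 ± 0.51 and C1QB at 8.34 ± 0.38 (at least 324-fold), in erythroid and leukocyte lists with no call. Of 27 colonocyte differentiation genes 12 rose, and adjusted over the list alone 13. Among them were ANPEP (5.56), APOA4 (5.02) and the fatty acid carrier FABP2 (at least 19-fold), and the list had adjusted p = 0.00201, and adjusted p = 0.658 with an estimated correlation. Of 27 NF-kB targets and chemokines 10 rose and 1 fell (adjusted over the list alone 10 and 1). Among them were IL32 (4.13) and IL1B (2.18), and the list had adjusted p = 0.00747, and adjusted p = 0.658 with an estimated correlation. Of 25 hypoxia genes 11 fell (adjusted over the list alone 11), with VLDLR at -3.73, ANGPTL4 at -2.77 and DDIT4 at -2.10 (adjusted p = 1.61e-05, and adjusted p = 0.658 with an estimated correlation). Of 16 glycolysis genes 4 fell (adjusted over the list alone 4). Among them were ALDOC (-2.50) and ENO2 (-1.93), and the list had adjusted p = 3.12e-06, and adjusted p = 0.136 with an estimated correlation. Of 25 cholesterol synthesis genes 7 fell (adjusted over the list alone 7). Among them were MSMO1 (-2.19), INSIG1 (-2.10) and IDI1 (-1.73), and the list had adjusted p = 0.00747, and adjusted p = 0.658 with an estimated correlation. Of 25 genes of the amino acid response 8 fell and 2 rose (adjusted over the list alone 8 and 2), with NUPR1 at -3.93 (adjusted p = 0.0161, and adjusted p = 0.658 with an estimated correlation). Mitosis (2 down of 22), oxidative phosphorylation (1 down of 23, SDHB at -1.03, but -0.81 without in vivo array 4) and heat shock (1 up, 1 down of 20, CRYAB at 2.67 and DNAJA1 at -1.14, but -0.91 without in vivo array 2) passed with adjusted p of 0.0193, 0.0161 and 0.0499, each with adjusted p = 0.658 with an estimated correlation. Adjusted over the list alone these 3 had the same counts. Without in vivo array 4 the first pair was lost (adjusted p = 0.121 and 0.119), and the heat shock call was lost without any of 12 arrays (adjusted p up to 0.157). In all 11 lists passed, 4 upward and 7 downward. The share of called genes that were higher in vivo was 57.4%, but 31.8% with arrays scaled to their median, and 5096 genes were called with the replicate number as a block.

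The 4 secondary comparisons complete the set, all between slides (n = 4 arrays per group). In vivo metastasis against lung biomatrix called 5886 genes, 4183 higher and 1703 lower. COL1A2 (at least 2770-fold) and DCN (11.37 ± 0.31, other probe 6.07) rose most, and CLEC3A (at least 2180-fold), FGF19 (-8.34 ± 0.41) and the receptor TEK (at least 93.8-fold) fell most. There 17 lists passed, and those of fibroblasts (10 up of 18) and mesenchymal transition (10 up of 14) also passed with an estimated correlation (adjusted p = 0.00606 and 0.0108). The share higher was 71.1%, but 51.8% with quantile normalization, 58.1% with normexp and quantile normalization and 25.2% with arrays scaled to their median. In vivo metastasis against Matrigel called 8583 genes, 4300 higher and 4283 lower. DCN (at least 4050-fold, other probe 5.26), COL1A2 (at least 1130-fold) and NCAM1 (at least 331-fold) rose most, and ALB (at least 248-fold), CLEC3A (at least 109-fold) and RNF150 (-6.72 ± 0.78, on a probe with a run of 9 bases of alternating G and A) fell most. Of its 17 lists only that of fibroblasts (10 up, 2 down of 18) passed with an estimated correlation (adjusted p = 0.0165), and on probes well above background on all 20 arrays it was lost (mean 1.06 after 3.54, adjusted p = 0.147). In this comparison ALB stood at -1.06 and CLEC3A at -4.53 without Matrigel arrays 2, 3 and 4 and plastic array 4, both still called. Liver biomatrix against Matrigel called 7451 genes, 3375 higher and 4076 lower, with the largest rises in LYPD8 (6.52 ± 0.79), HAPLN2 (6.39 ± 0.32) and SUCNR1 (at least 62-fold) and the largest falls in ALB (at least 313-fold), IGF2BP1 (at least 113-fold) and C4orf51 (-6.79 ± 0.71, on a probe with a run of 8 bases of alternating G and A). The share higher was 45.3%, but 31.8% with normexp and 59% with arrays scaled to their median. Lung biomatrix against Matrigel called 9293 genes, 3594 higher and 5699 lower, with the largest rises in CLDN2 (7.27 ± 0.55), C5orf58 (6.62 ± 0.37) and SLC14A1 (6.30 ± 1.39, other probes 5.39 and 5.59) and the largest falls in the fetal liver protein AFP (at least 1540-fold), HSPA6 (-10.51 ± 0.89, other probes -6.12 and -1.20) and RNF150 (at least 1100-fold, on its probe with a run of 9 such bases). Without Matrigel arrays 2, 3 and 4 and plastic array 4, AFP stood at -0.41 here with no call, and for liver biomatrix LYPD8 stood at 3.42, ALB at -1.13 and IGF2BP1 at -1.42, all still called. The share higher was 38.7%, but 22.7% with normexp, 52.8% with quantile normalization, 50.4% with normexp and quantile normalization and 65.5% with arrays scaled to their median. In these last 2 comparisons 11 and 15 lists passed, and 0 and 0 with an estimated correlation. With the replicate number as a block these 4 comparisons called 5892, 8587, 7440 and 9284 genes.

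The distance to the in vivo metastases asked which culture lay closest to the tumours across all 25322 genes. The noise-corrected mean squared log2 difference was 0.937 for liver biomatrix, 1.24 for lung biomatrix, 1.56 for plastic and 1.57 for Matrigel. Single arrays, without that correction, lay at 1.16 to 1.21 for liver and 1.41 to 1.44 for lung biomatrix. They lay at 1.58 to 1.94 for plastic and 1.68 to 2.06 for Matrigel. Each liver biomatrix array was thus nearer than each lung biomatrix array, and these nearer than each plastic or Matrigel array. Differences were tested over the 24952 genes with a value on all 20 arrays, so they differ slightly from those of these distances. Liver biomatrix was closer than lung biomatrix by 0.306, than plastic by 0.632 and than Matrigel by 0.64, and lung biomatrix was closer than plastic by 0.327 and than Matrigel by 0.334. Each of these 5 differences had an exact permutation p of 0.0286, the smallest that 70 assignments allow, and adjusted p = 0.0343 over the 6 pairs. Plastic and Matrigel differed by -0.00731 (exact permutation p = 0.943). Without any one of the 8 liver and lung biomatrix arrays these 5 differences kept their sign with adjusted p between 0.0571 and 0.274, and without Matrigel array 3 that of Matrigel and lung biomatrix had adjusted p = 0.0686. The in vivo arrays were alone on their slide, so the distances include any difference between slides, and the host-type transcripts of the metastases. Without the cell type marker lists, which removes listed markers only, the distances were 0.901 for liver biomatrix, 1.2 for lung biomatrix and 1.53 for plastic and Matrigel. With normexp background correction none of the 5 differences was called. Liver biomatrix was then closer than lung biomatrix and plastic by 0.245 each and than Matrigel by 0.301 (each adjusted p = 0.0571). Lung biomatrix was closer than Matrigel by 0.0566 (adjusted p = 0.129) and differed from plastic by -4.38e-05.

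**Figure D4:**
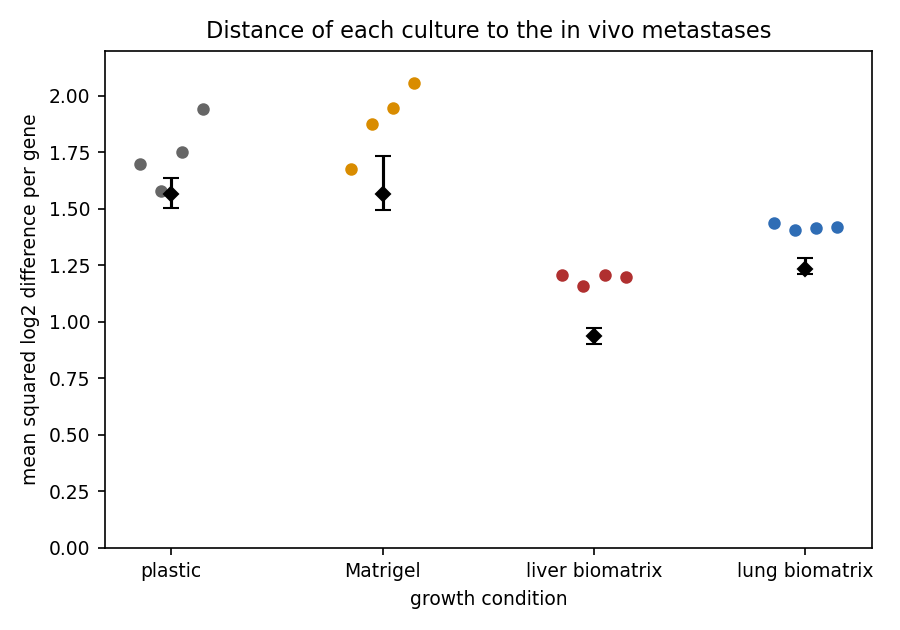
Squared log2 distance of each culture array to the mean of the in vivo metastases (points, mean over 25322 genes) and the noise-corrected distance of the group (diamonds). Whiskers run from the lowest to the highest group distance with 1 culture or in vivo array left out. Liver biomatrix arrays lie between 1.16 and 1.21, below all others, and plastic and Matrigel arrays lie between 1.58 and 2.06.

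The comparisons against plastic share their plastic arrays, so common changes were set beside fits with those arrays split. Liver biomatrix and in vivo metastasis had the most genes called the same way, 2382 up and 2105 down, against 743.7 and 557.7 for independent lists. Liver and lung biomatrix shared 1915 up and 2207 down, lung biomatrix and in vivo metastasis 1641 up and 1903 down, Matrigel and liver biomatrix 1429 up and 1196 down, and Matrigel and in vivo metastasis 1169 up and 1032 down. Matrigel and lung biomatrix shared 521 up and 776 down, with 602 genes called in opposite directions. With 2 plastic arrays for each comparison, the median numbers called the same way were 3827, 3684, 3075, 2303, 1676 and 1132 in that order. Simulated unchanged groups set against one simulated plastic group shared 0 genes, with a correlation across genes of 0.508 and a covariance of 0.0475. No gene was changed there, so 0 shared genes was nearly fixed in advance, and that correlation came from the shared group alone. In the data the covariances were 0.167 to 0.986, all above the simulated one. The correlations of Matrigel were 0.151 with lung biomatrix, 0.38 with in vivo metastasis and 0.483 with liver biomatrix. These 3 of the 6 lay below the simulated one, which holds noise only and is no yardstick for them. Against plastic, 337 genes were called higher and 456 lower under all 4 other conditions. Liver against lung biomatrix and Matrigel against plastic share no arrays and lie each within a slide. Across genes their differences correlated at 0.447, where genes are not independent replicates, with 1228 genes called up in both, 558 down in both and 214 in opposite directions. The genes up in both include ANGPTL4, ENO2 and CXCL8.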

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

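The tests of slides or scans for the G and A runs, all those of the liver-type transcripts, and those of a mesenchymal change and of slides or scans for the metastases were chosen only after the result was seen. In 185 groups of 4 array means of a gene list, 11 (5.95%) had 1 array far from the other 3, and 0 of 35 groups of other array measures did, where chance gives about 1 in 20. Of these 11, 4 fell on Matrigel array 1. There the mean log2 signal of DNA replication was 1.28, against 0.89 to 0.93 on the other Matrigel arrays. The hypoxia response stood at 2.69 on it, against 4.00 to 4.08. Matrix proteases and inhibitors stood at -0.89 on it, against -0.52 to -0.46. The amino acid response stood at 2.85 on it, against 3.58 to 3.65. On liver biomatrix array 4 cholesterol synthesis stood at 2.81, against 2.96 to 2.97. On liver biomatrix array 1 housekeeping genes stood at 5.51, against 5.73 to 5.74. On plastic array 2 fatty acid oxidation and ketogenesis stood at 1.17, against 0.98 to 1.01. On lung biomatrix array 4 the immediate early and AP-1 genes stood at 0.16, against 0.22 to 0.23. In vivo array 2 had a mesenchymal transition mean of -2.22, against -1.81 to -1.76. In vivo array 1 had an NF-kB and chemokine mean of -0.72, against -1.10 to -1.07. In vivo array 4 had an erythroid mean of -3.14, against -2.55 to -2.51.

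Of 73 probes with a run of 9 or more bases of alternating G and A, 18 had other probes of the same gene, and these 18 had a median log2 difference of lung biomatrix from Matrigel of -3.54 (quartiles -5.34 to -2.02). The other probes had a median of -0.0663 (quartiles -0.988 to 0.41), and the repeat probe lay lower by a median of -3.47 (quartiles -4.58 to -2.76), which argues against a change in the named transcripts. Between liver and lung biomatrix, on one slide, the repeat probes differed by a median of 3.74 (quartiles 1.23 to 4.45), which argues against slides or scans as the whole cause. Labelled material that binds the repeat may therefore explain the pattern, as a hypothesis, and what that material was remains open.

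Liver-type transcripts were high on Matrigel arrays 2, 3 and 4, where 15, 11 and 15 of 27 hepatocyte markers lay 2 or more log2 units above plastic arrays 1 to 3, and ALB had a standard deviation of 4.90 over the 4 Matrigel arrays against 0.54 or less on liver biomatrix, lung biomatrix and in vivo. On Matrigel array 1, 1 of 27 was raised, but the pattern was picked for that absence, so a response of the cells to Matrigel stays open. Across all tested genes Matrigel array 1 correlated with Matrigel arrays 2 to 4 at 0.971 or higher and with any other array at 0.968 or lower. It thus lay nearest to its own group, but by a margin of 0.00278 for which no yardstick was set. Whether Matrigel arrays 2 to 4 were mislabelled, or came from outside the series, was not tested. A mislabelled array therefore stays open. Of 1671 genes that lay 2 or more from plastic arrays 1 to 3 on Matrigel arrays 2 to 4, 1559 (93.3%) changed the same way on Matrigel array 1. No array of another group was set beside this share, so it does not bear on the label. RNA of another cell line or cell type mixed into those samples may be a source. The data leave it open too. Plastic array 4 was the highest plastic array for 35.4% of the 113 probes that were on in only those 3 Matrigel arrays. Other sets of 3 arrays of a culture had 0 to 41 such probes, but the 3 Matrigel arrays were picked for the pattern. A response of the cells, mixed RNA and a mislabelled array cannot be told apart.

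Fibroblast, leukocyte and other host-type transcripts were high in the in vivo metastases, with mean log2 signals of 5.07 for DCN, 4.90 for COL1A1 and 2.67 for HBA2. A mesenchymal change of the tumour cells is argued against as the whole cause, as the 24 epithelial junction genes had a median of 0.484 above plastic (quartiles 0.264 to 1.14), with 7 called higher and 0 lower. Mouse RNA of host cells that binds part of the human probes may be a source, but only 3 of 23 such genes had other probes, of which 5 of 7 (71.4%) lay within 1 log2 unit of plastic. For the 6 probes with other genes of as large a rise to compare, which left out that of DCN at 5.94, the share was 83.3% (interval 35.9% to 99.6%) against 57.9%. With so few probes the gap of 25.4 points cannot decide whether mouse RNA was bound. The slide of the metastases held 0 arrays of other groups, so a difference between slides or scans cannot be told apart from the group.

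For each of the 10 comparisons all 35 ways to split the 8 arrays into 4 and 4 were fitted. In each, 1 of the 35, the real split, called as many genes, the smallest share that 35 splits allow. A wrong split puts the group difference into the spread between arrays, which lowers its count. The counts of the other splits therefore do not measure chance, and chance was not excluded. The real count and the highest of the other splits were 5635 and 223 for Matrigel against plastic, 8196 and 1 for liver biomatrix against plastic, 6843 and 1 for lung biomatrix against plastic, and 8013 and 10 for in vivo metastasis against plastic. They were 4310 and 11 for liver against lung biomatrix, 5097 and 43 for in vivo metastasis against liver biomatrix, and 5886 and 4 for in vivo metastasis against lung biomatrix. Against Matrigel they were 8583 and 1306 for in vivo metastasis, 7451 and 627 for liver biomatrix, and 9293 and 115 for lung biomatrix.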

How the results depend on the processing

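Leaving out the probes with a G and A run, and leaving out Matrigel arrays 2, 3 and 4 with plastic array 4, were chosen only after the data were seen. With the deposited values, only the 2 groups compared, trended and robust variances, array weights or the replicate number as a block, every count of called genes stayed within 1.5 times its value (with the replicate block 5622 for Matrigel against plastic and 8196 against 8194 for liver biomatrix against plastic). With 1 array left out the called genes were 5335 to 5841 for Matrigel, 7844 to 8370 for liver biomatrix, 6561 to 6898 for lung biomatrix and 7703 to 8255 for in vivo metastasis against plastic, 4030 to 4643 for liver against lung biomatrix and 4947 to 5177 for in vivo metastasis against liver biomatrix. They were 5727 to 6294 for in vivo metastasis against lung biomatrix, and 8247 to 8893, 7104 to 7894 and 9129 to 9493 for in vivo metastasis, liver and lung biomatrix against Matrigel. The distances then were 1.51 to 1.64 for plastic, 1.49 to 1.73 for Matrigel, 0.903 to 0.973 for liver biomatrix and 1.21 to 1.28 for lung biomatrix. The differences in distance were 0.581 to 0.691 and 0.274 to 0.422 for plastic less liver and lung biomatrix. They were 0.566 to 0.808 and 0.252 to 0.502 for Matrigel less liver and lung biomatrix. Liver less lung biomatrix gave -0.386 to -0.245 and plastic less Matrigel -0.175 to 0.0675. Of 370 list results and 930 values of named genes, between 357 and 366 and between 916 and 929 then kept their direction and call. Under the 4 other normalizations 332 to 349 list results and 852 to 904 gene values kept both, 5 to 19 and 23 to 75 lost the call, and 15 to 21 and 2 to 10 gained it. With normexp background correction the called genes were 3680 for Matrigel, 5222 for liver biomatrix and 4755 for in vivo metastasis against plastic, 3071 for in vivo metastasis against liver biomatrix and 5134 against Matrigel, and 9 lists passed for lung biomatrix against plastic. The distances of plastic, Matrigel, liver and lung biomatrix were 0.753, 0.808, 0.515 and 0.757. Plastic and Matrigel less liver biomatrix gave 0.245 and 0.301, and liver less lung biomatrix -0.245, all with no call. Matrigel and plastic less lung biomatrix gave 0.0566, with no call, and -4.38e-05, a reversed sign. The genes shared against plastic were 1516 for Matrigel and liver biomatrix, 608 for Matrigel and lung biomatrix, 1182 for Matrigel and in vivo metastasis, 2414 for liver and lung biomatrix, 2567 for liver biomatrix and in vivo metastasis and 1894 for lung biomatrix and in vivo metastasis. SPATA18 (liver biomatrix against plastic) stood at 0.00, and SPP1 and ROBO4 (liver biomatrix against Matrigel) at -0.07 and -0.25. With normexp and quantile normalization the called genes were 4912, 3343 and 5007 for liver biomatrix, lung biomatrix and in vivo metastasis against plastic, 2376 for liver against lung biomatrix, 2588 and 2788 for in vivo metastasis against liver and lung biomatrix, and 5340, 4263 and 5586 for in vivo metastasis, liver and lung biomatrix against Matrigel. The distances, in the same order as above, were 0.806, 0.848, 0.437 and 0.52, and the shared genes 1574, 616, 1296, 2062, 2747 and 1898. Quantile normalization gave distances of 0.906 and 1.06 for liver and lung biomatrix, the mean of all probes of a gene 0.91 and 1.21, scaling to the median 0.986 and 1.29, with 8 lists for lung biomatrix against plastic, leaving out cell type marker lists 0.901 and 1.2, and leaving out probes with a G and A run 1.21 for lung biomatrix. Without a filter on dim probes the distances of plastic, Matrigel, liver and lung biomatrix were 1.26, 1.29, 0.766 and 1.03, on genes well above background on all 20 arrays 1.11, 1.11, 0.621 and 0.819, and as 1 minus the correlation 0.064, 0.0665, 0.0389 and 0.0442. With the fit on probes well above background on all 20 arrays the called genes were 4534 and 5207 for lung biomatrix and in vivo metastasis against plastic, and 2990, 3481 and 5551 for in vivo metastasis against liver biomatrix, lung biomatrix and Matrigel, where fewer genes were tested. There 6 lists passed for in vivo metastasis against liver biomatrix, the distances were 1.11, 1.12, 0.622 and 0.819, and the shared genes 823 for Matrigel and lung biomatrix, 2732 for liver and lung biomatrix and 2316 for lung biomatrix and in vivo metastasis. With treat, which by construction asks for a change beyond 1 log2 unit, the called genes were 1929, 3243, 2004 and 3287 for Matrigel, liver biomatrix, lung biomatrix and in vivo metastasis against plastic, 1188 for liver against lung biomatrix, 1282 and 1759 for in vivo metastasis against liver and lung biomatrix, and 3728, 2420 and 4322 for in vivo metastasis, liver and lung biomatrix against Matrigel, and the shared genes 757, 192, 487, 1108, 1425 and 909. With an estimated correlation in camera 1, 2, 2 and 1 lists passed for in vivo metastasis against plastic, liver biomatrix, lung biomatrix and Matrigel, and 0 for each of the other 6 comparisons. With fry in place of camera 24, 12 and 28 lists passed for liver biomatrix, lung biomatrix and in vivo metastasis against plastic, 29 for liver against lung biomatrix, 27 and 28 for in vivo metastasis against liver and lung biomatrix, and 21 and 32 for liver and lung biomatrix against Matrigel. With the mean of all probes of a gene LAMA4 (liver biomatrix against Matrigel) stood at -0.45. Without Matrigel arrays 2, 3 and 4 and plastic array 4 the mitosis list stood at 0.10 for Matrigel against plastic, SLC26A3 at -0.15, TIMP3 at -0.96 and APOA2 at -0.03. For in vivo metastasis against Matrigel TIMP3 stood at 0.19, ANKRD1 at 0.04 and ABCC2 at 0.10, and for lung biomatrix against Matrigel APOA4 at 0.31, LEF1 at 0.14 and SPARC at 0.08. For liver biomatrix against Matrigel it was BNIP3 0.62, APOA4 1.22, SLC26A3 0.70, SPARC 0.09, TIMP3 0.78, ANKRD1 0.17, STC2 0.24 and FBLN1 0.12. The differences in distance were then 0.582 and 0.276 for plastic less liver and lung biomatrix, 0.673 and 0.367 for Matrigel less liver and lung biomatrix and -0.306 for liver less lung biomatrix. With 1 Matrigel array left, its pairs had too few permutations for a call. Through the adjustment over all pairs the differences without Matrigel lost their call as well. Liver and lung biomatrix kept all their arrays and their permutations. Otherwise the cause was not tested. Between 61.1% and 75.2% of probes per array were well above background, so for genes dim in one group the size of a difference is uncertain and folds are given as bounds.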

Other observations

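The genes below were chosen after their values were seen. Cancer-testis antigens of the MAGEA family varied widely between arrays of one group. The standard deviation over the 4 in vivo metastases was 4.57 for MAGEA1, 3.95 for MAGEA4, 4.88 for MAGEA12, 6.06 for MAGEA2B and 5.83 for MAGEA6, against 0.34, 0.18, 0.18, 0.32 and 0.34 over the 4 plastic arrays. The group means were close, at -4.41 and -4.74 for MAGEA1, -5.22 and -5.74 for MAGEA4, -2.01 and -2.09 for MAGEA12, -1.10 and -0.99 for MAGEA2B, and 0.11 and -0.46 for MAGEA6. Over the 4 Matrigel arrays the standard deviations were 2.09, 1.81, 2.82, 3.15 and 3.85 in the same order.

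The deviations of arrays from their group means were compared between groups by replicate number. Over 40 pairs of groups and numbers the median correlation across genes was 0.008, from -0.129 to 0.275, with 3 above 0.1, and for 7 the array of the same number was the closest. The 3 above 0.1 were plastic array 4 with Matrigel array 4 (0.275) and in vivo array 4 (0.15), and plastic array 1 with in vivo array 1 (0.103). Mean spike-in signals relative to the 75th percentile were 0.47 in vivo, 0.10 on liver biomatrix, -0.11 on Matrigel, -0.75 on lung biomatrix and -1.45 on plastic.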
